A study of Rattus norvegicus with 8 samples.

How the data were processed

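Total RNA from the cortex of 8 rats, 4 controls and 4 after hypoxia-ischemia (HI), was labelled with Cy3 and hybridised to Agilent rat arrays, 1 animal per array, per the labels. The labels' protocols state that each RNA passed a check of purity and integrity. The authors' scanner files were made with Agilent Feature Extraction (version 9.5.3.1 per the file headers). They hold, per the file headers, an intensity for each spot: the processed signal, which is background-subtracted within the array, and the median spot and local background signals. The other columns used from these deposited files are flags for spots that are well above background, saturated or outliers. The deposited series table holds log2 values for each probe, of unstated centring. Set against the scanner values, its columns correlated at 0.9997 or higher with the log2 processed signal minus the array's 75th percentile, centred on each probe's median over the 8 arrays. Its column medians were 0.48 for control 1 and between -0.05 and 0.04 for the others. Its scale, centring and direction were all settled by this comparison, and it served as an alternative. Its 41088 rows include 76 control probes.

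Each array has 45018 spots, of which 1639 are controls and were left out. The other 43379 spots make 41012 probes, 40749 of them with 1 spot and 263 with 10. Values were log2 of the processed signal minus the array's 75th percentile (of these spots), so a level of 0 is the 75th percentile. Outlier-flagged spots were set to missing, spots of a probe were averaged, and 87 probe values were missing after this. Saturated spots were kept. A probe was kept if well above background on all arrays of at least 1 group, which left 24872 probes. The scanner files name each probe's target by an accession or a cluster name. Accessions were matched without version to the RefSeq transcripts of the GRCr8 rat assembly. A single gene was found for 10735 probes (26.2%), none matched several, and 30277 kept the name in the file. The array design predates that assembly, so no coordinates are given, and the assembly was used only for names and for which genes neighbour each other. A gene was represented by its kept probe with the highest mean over all 8 arrays, giving 21674 genes, 5950 with a symbol.

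The groups were compared with limma (3.58.1, in R 4.3.3) by lmFit and eBayes, with Benjamini-Hochberg adjustment over all genes tested. Fold changes are HI minus control on the log2 scale with limma's standard error, and a ± gives the SD. Where no array of a group had a probe of the gene well above background, the change is a bound. It sets the mean of the brighter group against the mean over the dimmer group's arrays of the higher of the lowest signal among probes well above background and the probe's own signal. The 31 gene lists were written from textbook knowledge before the data were examined, as were the tests of the groups and lists, the rule for named genes and the alternatives below except 1. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, over the 21630 genes with no missing value, and adjusted over the 30 lists tested. The sex-linked list had 0 measured genes. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move on balance in 1 direction. No list passed with either, and 2 and 7 lists had unadjusted p under 0.05. With fry's test for change in either direction 3 lists passed, the astrocyte, glucocorticoid-responsive and heat shock lists.

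The named genes were those with a symbol at an adjusted p under 0.05 and with groups that do not overlap, up to 15 in each direction by size of change. Added to these were the members of each list that passed, or the 2 with the smallest unadjusted p where none did, and Gfap, Aif1, Mbp, Slc17a7, Gad1, Pvalb, Bdnf and Slc12a5. Others named were chosen after their values were seen. Some genes that this rule picks are not reported here.

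The alternatives were normexp background correction (offset 50) with quantile or 75th percentile scaling, quantile scaling, the median, the authors' table, 2 other filters, the mean of a gene's probes, single probes, an intensity trend with a robust prior, array weights, a replicate block, and leaving out each array. Leaving out control 1 and HI 2 together was chosen after seeing the data. The mean spot signal was not used here, so normexp was run on the median spot signal. Slide and scan could not be fitted as blocks, since each group lay on 1 slide with 1 scan.

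The fit was tested on simulated data with 200 of 21630 genes changed, using each gene's mean and within-group spread from the real arrays for the HI against control comparison. It recovered 16% of 50 genes changed 1.5-fold, 46% at 2-fold, 80% at 4-fold and 90% at 8-fold, with 13 false calls among 129, and called 0 genes when none had been changed. The 13 false calls among 129 are a larger share than the 0.05 of the adjusted threshold, in a single simulated data set. The simulated values were independent between genes, with the same spread on all arrays. The simulation therefore does not cover an array that lies apart, such as control 1, or genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.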

Results

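Gene expression was profiled in the cerebral cortex of 8-week-old Wistar rats, with 1 array per animal. In 4 animals the left carotid artery had been cut at 7 days of age and followed by 1 h in 8% oxygen at 33 °C, a procedure that injures the hemisphere on the side of the cut artery (hypoxia-ischemia, HI). The 4 control animals had no insult. The tissue was the cortex of the opposite hemisphere, and of the matching side in controls, so the comparison asks how cortex away from the injured side differs in the mature animal. On each array 57.6% to 66.2% of the probes were well above background. The 75th percentile of the processed intensity lay between 436.1 and 510.2 on 7 arrays and at 234.2 on the array of control 1, whose correlations with the other arrays were 0.904 to 0.926 where those among the other 7 were 0.973 to 0.995. All 4 control arrays were on 1 slide and all 4 HI arrays on another, each slide with its own scan, so slide, scan and group cannot be told apart. The number of arrays limits the precision of every value.

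**Figure D1:**
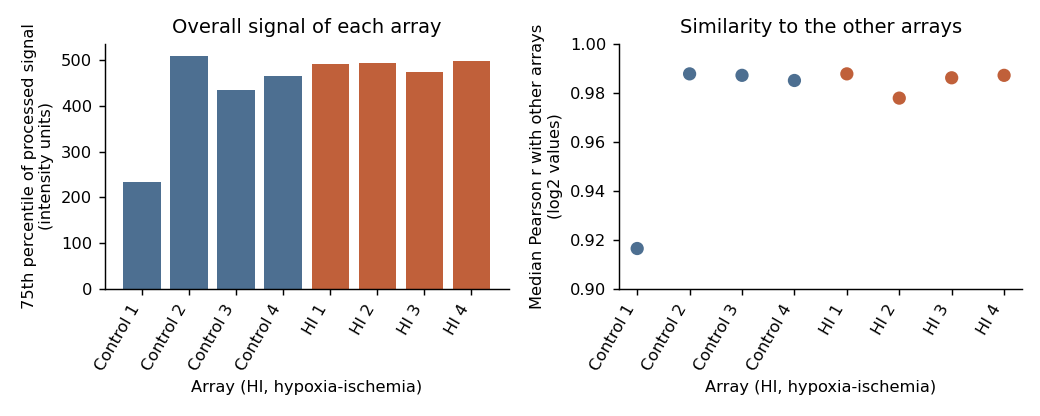
Left, the 75th percentile of processed signal (intensity units) of each array, as bars from 0; right, each array's median Pearson r with the other arrays over log2 values of probes well above background on all arrays (the axis starts at 0.9). Controls are blue and hypoxia-ischemia (HI) arrays orange; control 1 stands at 234.2 and r = 0.917, and the other 7 arrays at 436.1 or higher and r = 0.978 or higher.

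At 8 weeks of age, 199 of the 21674 genes tested differed between HI and control cortex at an adjusted p under 0.05, 42 higher and 157 lower after HI. Among the 23 of them that have a gene symbol, Kynu, the kynureninase of tryptophan breakdown, fell at least 1.74-fold (adjusted p = 2.68e-05), and Iqcm fell by 2.99 on the log2 scale (SE 0.158, adjusted p = 7.5e-05). Ccn1, a secreted matrix protein induced by growth factors, fell by 2.40 (SE 0.279, adjusted p = 0.00574), and Sv2b, a synaptic vesicle glycoprotein, fell by 1.85 (SE 0.123, adjusted p = 0.000238). Ptges, which makes prostaglandin E2, rose by 2.70 (SE 0.455, adjusted p = 0.0439), and Rhoj, a small GTPase of endothelial cells, rose at least 1.39-fold (adjusted p = 0.00374).

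Kynu measured -4.24 ± 0.22 (SD, n = 4) in controls, in log2 units over the array's 75th percentile, and was not well above background on any HI array, which makes its fall a lower bound (fitted log2 change -3.12, SE 0.134). Rhoj was not well above background on any control array and reached -4.26 ± 0.48 (SD, n = 4) after HI (fitted log2 change 2.19, SE 0.234). Iqcm went from 0.01 ± 0.22 to -2.98 ± 0.22 (SD, n = 4 each), and Sv2b from 7.20 ± 0.12 to 5.34 ± 0.17 (SD, n = 4 each). A second, dimmer Sv2b probe gave a log2 change of -0.27 with an unadjusted p of 0.407, so the fall rests on the brighter probe. Ccn1 went from -2.38 ± 0.51 to -4.78 ± 0.34 and was well above background on 3 of the 4 HI arrays. Ptges went from -4.38 ± 0.89 to -1.69 ± 0.53 and was well above background on 3 of the 4 control arrays.

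Other genes that fell were Adcy10, the soluble adenylyl cyclase (log2 change -2.15, adjusted p = 0.0141), Katnal1, a microtubule-severing ATPase (-1.50, 0.0167), Serpina5, the protein C inhibitor (-1.19, 0.0112), Apold1, an early-response gene of endothelial cells (-1.04, 0.0445), and Fbxo32, the ubiquitin ligase atrogin-1 (-1.01, 0.0485). Smaller falls were found in Nat8b (-0.71, 0.0262) and in Pgap2, which remodels GPI anchors (-0.69, 0.0193). Other rises lay between 0.64 and 1.24 on the log2 scale. They included Cblc, a ubiquitin ligase of the Cbl family (1.24), Mia (1.01), Cenpl, a centromere protein (0.94), Prr5, a subunit of mTOR complex 2 (0.93), Sft2d2 (0.89), the olfactory receptor Or2a57 (0.88), Prrc1 (0.84), Dnase1 (0.79) and Pigl, of GPI anchor synthesis (0.64), with adjusted p between 0.00917 and 0.046.

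**Figure D2:**
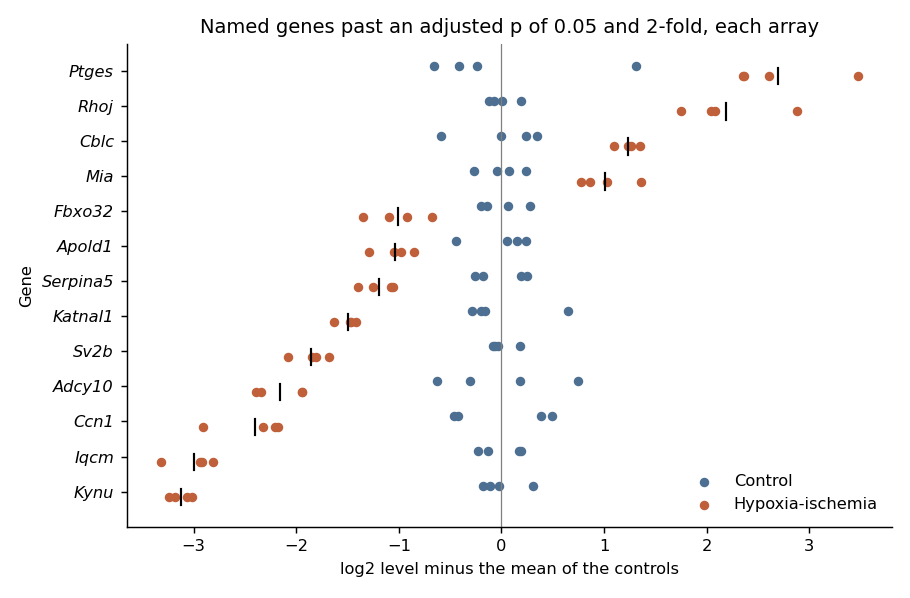
The horizontal axis gives the log2 level on each array minus the mean of the 4 controls, for the genes with a symbol past an adjusted p of 0.05 and changed at least 2-fold in the fit (vertical axis). Blue points are control arrays, orange points HI arrays, and black bars the HI means; fitted changes run from -3.12 for Kynu, not well above background after HI, to 2.70 for Ptges.

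The remaining 176 genes, 30 higher and 146 lower, carry only an accession or cluster name. The 23 with a symbol were 12 higher and 11 lower, so the excess of lower genes lay in those without a symbol. Genes with a symbol were 5950 of the 21674 tested, a larger share than 23 of 199. Among all 199 genes, 46 differed by over 8-fold, 44 of them lower, when genes not well above background in a group were taken at their bound; none of the 46 has a symbol. TC560869 and TC539365 were not well above background on any HI array and were at least 107-fold and 70.8-fold lower than in controls. XM_345411 rose by 4.98 on the log2 scale (SE 0.273, adjusted p = 9.55e-05). Of 13 genes past the threshold with more than 1 kept probe, 10 had all probes changed in the same direction at an unadjusted p under 0.05, and NM_001014221 fell on each of its 7 probes. The exceptions were Sv2b, XM_217367 (a probe at -0.04, unadjusted p = 0.776) and XM_228462 (a probe at 0.13, 0.227). Among the 10, NM_001014221, XM_001056098, XM_001063747, XM_343674 and XM_576797 had fitted falls over 8-fold. Many probes with such falls may read a single family of shared sequence. In that case the agreement of their probes is not independent evidence.

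With a minimum change of 2-fold and an unadjusted p under 0.05, 411 genes differed, 146 higher and 265 lower, of which 66 have a symbol. This count was 159 (31 higher and 128 lower) and 163 (24 and 139) after normexp background correction with quantile and 75th percentile scaling, and 852 (217 and 635) with no filter on dim probes. The array of control 1 widened the spread of the controls: without it 793 genes passed the adjusted threshold, 329 higher and 464 lower, and all 199 were among them. Leaving out control 4, HI 1, HI 3 or HI 4 gave 129, 125, 116 and 130 genes. Of the 23 genes with a symbol Kynu, Iqcm, Ccn1, Sv2b and Rhoj passed whichever single array was left out. Of the others Serpina5 passed in 6 of these 8 fits, Or2a57 in 5, Adcy10 in 4, and Katnal1 and Cenpl in 3. Cblc, Apold1, Nat8b and Pgap2 passed in 2. Ptges, Mia, Prr5, Sft2d2, Prrc1, Dnase1, Pigl and Fbxo32 passed only without control 1. After normexp correction 16 of the 23 passed with quantile scaling and 10 with 75th percentile scaling. Rhoj passed with neither (log2 change 0.36, adjusted p = 0.244, and 0.12, 0.753), and with 75th percentile scaling the genes that did not pass included Kynu (-0.69, 0.161), Ptges (1.12, 0.206), Cblc (0.20, 0.592), Prr5 (0.16, 0.609), Pigl (0.11, 0.628) and Fbxo32 (-0.41, 0.423).

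Of the 31 gene lists fixed in advance, 30 had enough measured genes, and 4 shifted as a whole relative to the other genes at an adjusted p under 0.05. Glucocorticoid-responsive genes were shifted up, with a median log2 change of 0.57 and 8 of 9 measured members above 0 (adjusted p = 0.00415). The immediate early genes, transcription factors and other genes induced by neuronal activity, were shifted down, with a median of -0.40 and 12 of 14 members below 0 (adjusted p = 0.00731). Red blood cell genes and meningeal and fibroblast markers were shifted up, with medians of 0.94 over 4 members and 1.47 over 9 members (adjusted p = 0.00415 for each). When camera estimated the correlation between genes from the data, none of the 4 passed. Its adjusted p was 0.337 for the glucocorticoid-responsive genes and 0.444 for the immediate early genes. It was 0.444 for the red blood cell genes and 0.597 for the meningeal markers. The estimated correlations were 0.00419, 0.0994, 0.73 and 0.749 in the same order. For the glucocorticoid-responsive genes the estimate lay below the preset 0.01, so correlation between these genes does not account for the loss.

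Among the immediate early genes Ier2 fell, with a log2 change of -0.58 (SE 0.134, adjusted p = 0.0359 adjusted over the list alone and 0.139 over all genes tested). Egr1 (-0.58), Nr4a1 (-0.74) and Btg2 (-0.43) had unadjusted p under 0.05 and passed neither adjustment. No glucocorticoid-responsive gene passed by itself. Sult1a1, a sulfotransferase, had the smallest p (log2 change 1.19, SE 0.358, adjusted p = 0.0877 adjusted over the list alone), followed by Fkbp5, a chaperone of the glucocorticoid receptor (0.57, SE 0.195, 0.0877), and Tsc22d3, also called Gilz, measured 0.68. Of the 4 red blood cell genes Hbb (0.95, SE 0.265), Alas2, which starts heme synthesis (0.94, SE 0.284), and Slc4a1, the band 3 anion exchanger (0.96, SE 0.33), rose when adjusted over the list alone (0.0219, 0.0219 and 0.0258). Over all genes tested they did not pass (0.228, 0.273 and 0.34).

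The meningeal markers were all above 0, and none passed by itself. The smallest unadjusted p were those of Igf2 (log2 change 1.81, SE 0.819, adjusted p = 0.15 adjusted over the list alone) and the insulin-like growth factor binding protein Igfbp2 (2.81, SE 1.29, 0.15), which choroid plexus expresses too. The markers were highest in HI 2: Col1a2, of type I collagen, measured 5.28 there and 0.69 to 1.91 on the other 7 arrays, and the meningeal transporter Slc6a13 measured 2.35 against -1.51 to -1.12. Without HI 2 the list still passed at the preset correlation, with a median of 0.78 (adjusted p = 0.00986). With all arrays its adjusted p = 0.597 with an estimated correlation, which was 0.749 between its genes. Choroid plexus genes also differed between animals, across both groups. Ttr, the transthyretin that choroid plexus secretes, measured 7.62 in control 2, 8.00 in HI 3, 7.83 in HI 4, 3.86 in HI 2 and 1.41 or less on the other arrays. The choroid plexus and ependymal list had a median change of 1.62 over 6 members (adjusted p = 0.458), with Kcnj13, a potassium channel (3.60, SE 2.09), and Ttr (3.18, SE 2.40) leading it. Kcnj13 measured 2.2 in control 2 and -4.89 or less in the other controls. The list's adjusted p was 0.0454 without control 2 and 0.862 without control 1, where its median was 0.96. Without control 1 the meningeal list no longer passed (adjusted p = 0.0603, the highest of 8 fits without 1 array, from 4.58e-05), and without control 1 and HI 2 together, a choice made after seeing the data, its adjusted p was 0.112 with a median of 0.50. In that fit the glucocorticoid-responsive, red blood cell and immediate early lists had adjusted p of 0.000585, 0.0464 and 0.0464. The immediate early list did not pass without control 4 (adjusted p = 0.052, the highest of these 8 fits, from 0.00121), and the glucocorticoid-responsive and red blood cell lists passed in all 8. All of these fits use the preset correlation. With all arrays none of the 4 lists passed with an estimated correlation (adjusted p = 0.337 to 0.597) or by fry (0.0621 to 0.376).

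**Figure D3:**
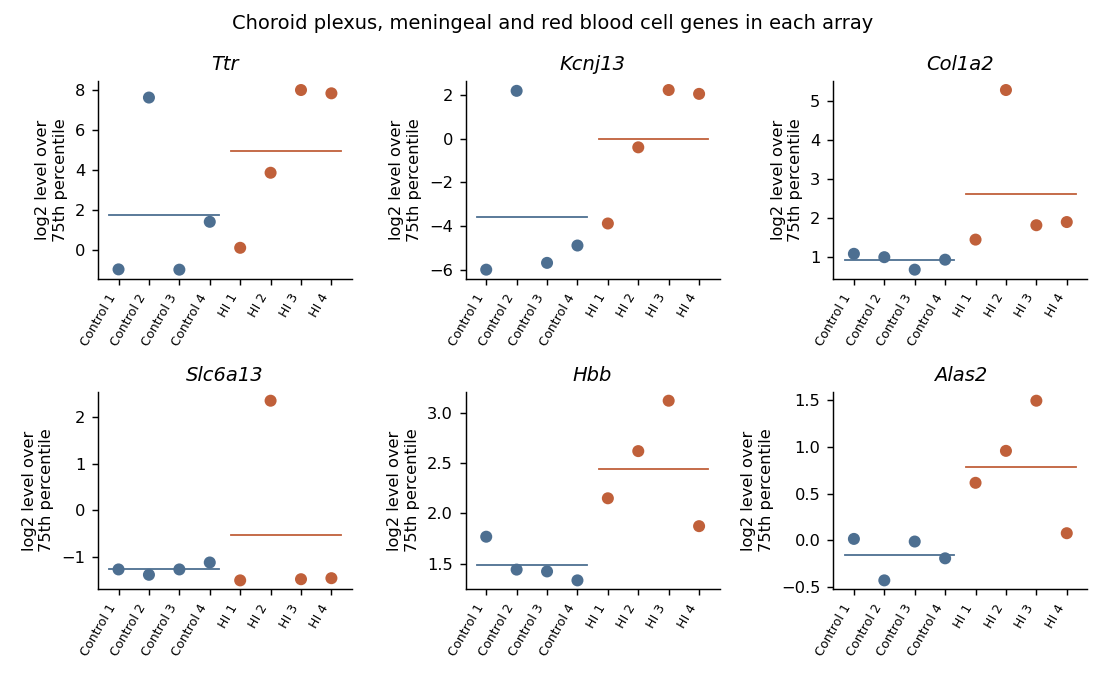
Each panel gives the log2 level over the array's 75th percentile (vertical axis) of 1 gene on each array: Ttr and Kcnj13 for choroid plexus, Col1a2 and Slc6a13 for meninges, Hbb and Alas2 for red blood cells. Points are arrays and lines group means (control blue, HI orange); Ttr is high in control 2, HI 3 and HI 4, while Col1a2 and Slc6a13 stand out in HI 2 alone at 5.28 and 2.35.

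None of the 313 measured list members passed limma's test adjusted over all genes, although 39 had an unadjusted p under 0.05, 18 higher and 21 lower, and 11 passed without control 1. Of all genes, 2296 of 21674 had an unadjusted p under 0.05, and 793 of 21794 passed without control 1. Both counts of list members are near these shares. Adjusted over the list alone, 15 members passed, of which S100b and Cox5a did so whichever single array was left out.

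The astrocyte markers went in both directions, with 1 of 11 higher and 2 lower adjusted over the list alone. S100b, a calcium-binding protein, fell by 0.96 (SE 0.199, adjusted over the list alone 0.0143), and Atp1b2, a subunit of the sodium pump, fell by 0.59 (SE 0.179, 0.0415). Gjb6, connexin 30, rose by 0.88 (SE 0.213, 0.018). Among the 7 reactive astrocyte genes the small heat shock protein Hspb1 rose by 0.90 (SE 0.249, 0.0486 adjusted over the list alone), and the list's median of 0.51 did not pass (adjusted p = 0.0839). Without 1 array the list's adjusted p ran from 0.0143, without HI 1, to 0.281, without control 3. It was 0.0416 to 0.12 over the scalings, and the median was 0.25 without HI 2. Gfap, the intermediate filament of reactive astrocytes, measured -0.06 ± 0.78 in controls and 0.45 ± 0.18 after HI (SD, n = 4 each; adjusted p = 0.583), a difference of 0.51 that was 0.13 without control 1. The 11 microglia and macrophage markers had a median of 0.07 (adjusted p = 0.356), with 0.80 for Itgam (SE 0.245), 0.59 for C1qc (SE 0.217) and 0.00 for Aif1, the microglial protein Iba1 (SE 0.146, adjusted p = 0.988).

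Myelin and oligodendrocyte genes had 8 members above 0 and 6 below, and none of the 14 passed. Opalin (log2 change -0.86, SE 0.219) and Mog (-0.62, SE 0.216) had the smallest unadjusted p, and Mbp, the myelin basic protein, measured 0.32 (SE 0.64, adjusted p = 0.791) and -0.40 without control 1. All 4 oligodendrocyte precursor genes lay below 0, with a median of -0.26 (adjusted p = 0.0672), led by Bcas1 (-0.50, SE 0.179) and Tnr (-0.33, SE 0.131). This list passed without HI 1 (0.0425) or HI 3 (0.0396) and was at up to 0.172 in the other fits without 1 array. Over the scalings its adjusted p was 0.0464 to 0.13. The endothelial list (median 0.25, adjusted p = 0.55), with Kdr at -0.57 (SE 0.212) and Emcn at 0.61 (SE 0.305), and the mural cell list (median 0.15, adjusted p = 0.55), with Pdgfrb at -0.54 (SE 0.279) and Rgs5 at 0.15 (SE 0.0936), held no member past either adjustment. Without control 1 Kdr measured -0.37, Emcn 0.29 and Pdgfrb -0.27. The mural median was 0.25 without control 1 and 0.03 without HI 2.

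Of the interneuron markers Gad2, an enzyme of GABA synthesis, fell by 0.67 (SE 0.164, 0.0408 adjusted over the list alone), and the other 11 passed neither adjustment. Below 0 were 8 of the 12 members, among them Calb2 (log2 change -0.81, SE 0.279) and Slc32a1 (-0.35, SE 0.17). Gad1 (0.26, SE 0.233) and Pvalb (-0.08, SE 0.273) measured 0.02 and 0.14 without control 1. The list's median was -0.13 (adjusted p = 0.498), and 0.09 without HI 2. The glutamatergic neuron markers had a median of -0.06 (adjusted p = 0.912), with 0.21 for the vesicular transporter Slc17a7 (SE 0.13) and -0.27 for Nrgn (SE 0.21; -0.09 without control 1). Of the striatum markers the opioid precursor Penk fell by 0.58 (SE 0.163, 0.0454 adjusted over the list alone; median of the list 0.02, adjusted p = 0.912). The hippocampus and thalamus markers had a median of -0.40 (adjusted p = 0.49), with Calb2 at -0.81 (SE 0.279) and Wfs1 at -0.62 (SE 0.865). Without HI 2, where Wfs1 measured -1.17 against 2.29 to 2.60 on the other HI arrays, that median was -0.03 and Wfs1 was at 0.29; without control 1 Wfs1 was at -0.98.

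Receptor genes did not shift as groups. The 16 glutamate receptors had a median of 0.03 (adjusted p = 0.846), with the AMPA receptor subunit Gria1 at 0.70 (SE 0.184, 0.0849 adjusted over the list alone) and Grin2c at -0.34 (SE 0.145). The 15 GABA receptor and chloride transporter genes had a median of -0.20 (adjusted p = 0.498), with Gabrd at -0.40 (SE 0.144) and the chloride extruder Slc12a5 at 0.01 (SE 0.109, adjusted p = 0.96). Their median was -0.05 without control 1. For the 16 monoamine and acetylcholine receptors the median was -0.03 (adjusted p = 0.965). Their smallest unadjusted p were those of Drd4, not well above background in any control and at least 1.55-fold higher after HI (adjusted p = 0.383), and Chrnb2 (-0.31, SE 0.175; -0.19 without control 1). Axon growth and plasticity genes had a median of -0.04 (adjusted p = 0.985), with Ntf3 at 0.43 (SE 0.305), Gap43 at -0.25 (SE 0.175) and Bdnf at 0.11 (SE 0.245, adjusted p = 0.806). These measured 0.19, -0.09 and -0.06 without control 1, and Ntf3 0.20 and Bdnf -0.03 without HI 2.

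Among the genes of metabolism and protein synthesis, Cox5a, a subunit of cytochrome c oxidase, fell by 1.01 (SE 0.191, 0.00994 adjusted over the list alone) while the median of the 14 oxidative phosphorylation genes was 0.16 (adjusted p = 0.498). That median was 0.04 without control 1. Of 23 cytosolic ribosomal protein genes Rpl6 fell by 0.44 (SE 0.0895, 0.0265) and Rps24 by 0.69 (SE 0.169, 0.0395), both adjusted over the list alone, and the list's median was -0.11 (adjusted p = 0.316). Of 10 heat shock and unfolded protein genes the chaperones Hspa5, of the endoplasmic reticulum, and Hsph1 rose by 0.47 (SE 0.105, 0.021) and 0.32 (SE 0.0938, 0.0494), with a list median of 0.22 (adjusted p = 0.152).

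In the other lists no member passed either adjustment. Hypoxia-responsive genes had a median of 0.20 (adjusted p = 0.316), with Hmox1 at 0.48 (SE 0.198) and Vegfa at -0.63 (SE 0.415). Without control 1 Hmox1 measured 0.28 and Vegfa -0.17, and the median was 0.1. Circadian clock genes had a median of 0.15 (adjusted p = 0.152), with Per1 at 0.51 (SE 0.233) and Per2 at 0.29 (SE 0.138). Over the scalings the adjusted p of the circadian list was 0.0361 to 0.225. Antioxidant genes had a median of 0.10 (adjusted p = 0.439), with Nqo1 at 0.64 (SE 0.297) and Sod1 at -0.20 (SE 0.165). Apoptosis genes had a median of 0.03 (adjusted p = 0.912), with Bak1 at -0.43 (SE 0.244) and Bid at 0.65 (SE 0.408). Cytokines and adhesion molecules had a median of 0.09 (adjusted p = 0.409), with Tgfb1 at 0.31 (SE 0.163) and Icam1 at 0.35 (SE 0.226). Interferon, MHC and complement genes had a median of 0.02 (adjusted p = 0.846), with C4a at 1.19 (SE 0.608) and Psmb9 at -0.34 (SE 0.214). Proliferation and immature neuron genes had a median of -0.04 (adjusted p = 0.846), with Dcx at -0.20 (SE 0.131) and Stmn1 at -0.21 (SE 0.197). Leaving out control 1 also made several of these changes smaller by over 1.5 times: Per1 measured 0.27, Nqo1 0.33, Sod1 -0.04, Bak1 -0.17, Bid 0.21, C4a 0.75 and Psmb9 -0.19 without it. Without HI 2 the same held for C4a (0.67), Icam1 (0.13), Tgfb1 (0.20) and Stmn1 (-0.06). The medians of the glutamatergic, glutamate receptor, monoamine, axon growth, interferon, apoptosis and proliferation lists changed sign under at least 1 other scaling. Without control 1 the medians of the myelin, striatum, interferon and apoptosis lists changed sign, and without HI 2 those of the glutamatergic, interneuron, glutamate receptor, monoamine, cytokine, interferon and apoptosis lists. In 5 lists, the glutamatergic, myelin, striatum, monoamine and axon growth lists, the median, the mean and the direction of the test differ in sign.

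**Figure D4:**
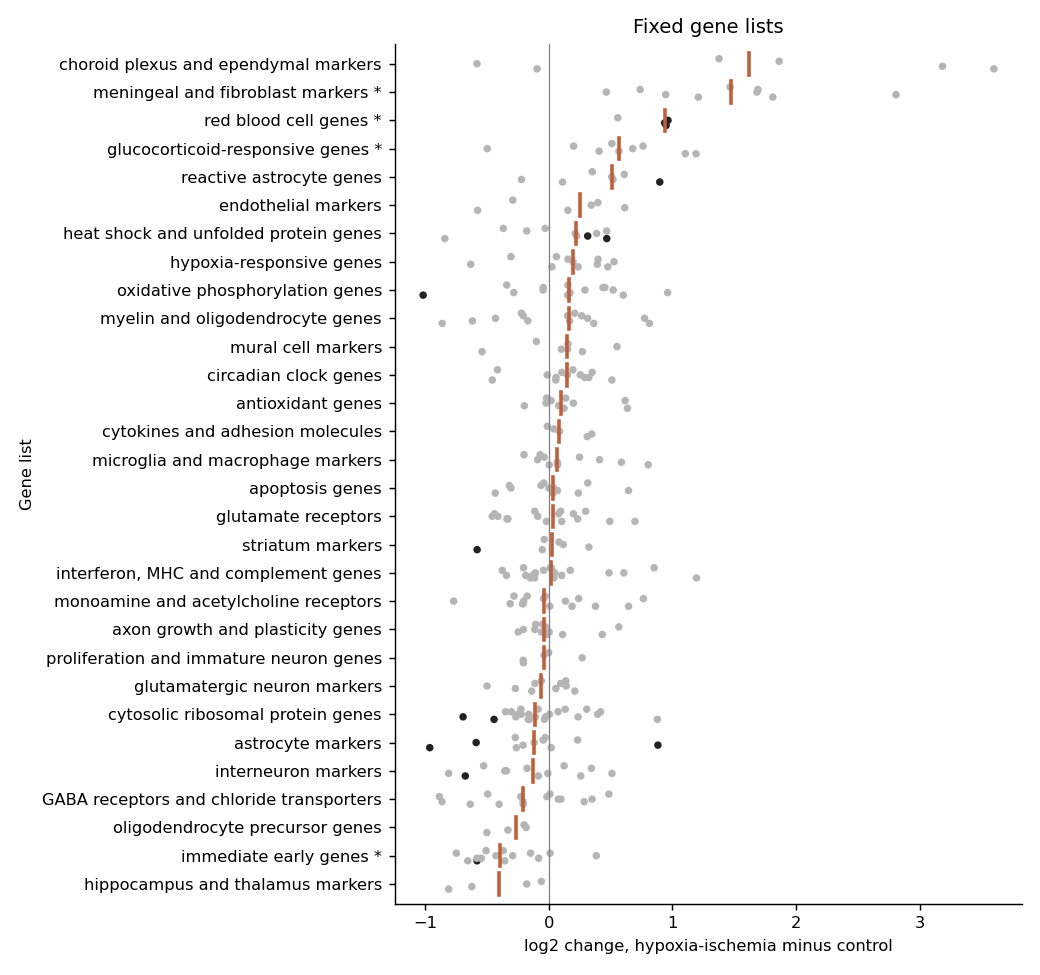
The horizontal axis gives the log2 change (HI minus control) of each measured member of the 30 tested gene lists (vertical axis). Points are genes, black where the adjusted p over the list alone is under 0.05, and orange bars are list medians. An asterisk marks the 4 lists past an adjusted p of 0.05 at the preset correlation, with medians of 1.47, 0.94, 0.57 and -0.40. None of the 4 passed with an estimated correlation.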

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

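Tests on the brightness of control 1, on shared sequence, on the spread of spots over the array, on the slide and on choroid plexus genes were chosen after the results were seen. Within each group of 4 arrays, a value was singled out when its gap to the nearest other, as a share of the group's range, exceeded Dixon's 95% critical value. Of 240 groups of values 23 met this, where chance gives about 1 in 20, or 12; 11 of them were on control 1 and 9 on HI 2. The values here are log2 differences from the mean of the other 3 arrays of the group, except for correlations.

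Control 1 stood apart in its median correlation with the other arrays, by -0.0702, and in Katnal1 (0.87), Pdgfrb (1.08), Hmox1 (-0.79), Vegfa (1.85), Ntf3 (-0.97), C4a (-1.77), Cox5a (0.78), Rps24 (0.59), Mbp (-2.85) and the mean of the hypoxia-responsive list (-0.162). HI 2 stood apart in its median correlation, by -0.00917, in S100b (-0.34), Wfs1 (-3.66), Bak1 (-0.145) and Pvalb (-0.73), and in the means of the myelin (-0.75), hippocampus and thalamus (-1.22), cytokine (0.60) and circadian clock (-0.081) lists. Control 2 stood apart in Kcnj13 (7.72) and Igf2 (2.40), and HI 1 in Per1 (0.28).

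On control 1, 5991 of 21865 probes well above background on all arrays lay over 2-fold from the mean of the other controls, against 154 to 686 on the other arrays. Less labelled RNA alone is argued against by the 5467 brightest of these probes, where its median correlation with the other arrays was still 0.895, against 0.962 or higher for the others. Another state of that animal's cortex is argued against as the main source, since in 1101 genes with several probes the deviations of 2 probes of a gene correlated at only 0.155 across genes. That correlation was 0.697 to 0.857 on the HI arrays and 0.19 to 0.493 on controls 2 to 4, so a low value is not peculiar to control 1, but its deviations had an SD of 0.971 where the others had 0.233 to 0.398. The spike-in control probes were not dim on control 1, whose median spike-in signal of 6923 was the highest of all arrays. Its 75th percentile over that signal was 0.0338, against 0.0772 to 0.0854 on the other arrays, so its sample RNA gave less signal. An effect on single probes may account for the departure. Whether it arose in labelling, in hybridization or from the amount or quality of that RNA was not told apart. No biological explanation given by the design applies to a single control.

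Of the 199 genes, 57 had a fitted change over 8-fold, 55 of them lower, although 11 of these were not well above background after HI and have bounds under 8-fold. For the 33 of them well above background on all arrays, within-group deviations over the 7 arrays other than control 1 had a mean pairwise correlation of 0.689, where the highest of 1000 random sets of 33 genes gave 0.134, and 29 of the 33 were lowest on HI 2. Many of these probes may read a single family of shared sequence, in which case their number overstates the number of separate changes. The correlation cannot tell this from separate genes that vary together for another reason, and no probe sequence was examined. The spots of the 57 genes were not gathered at 1 place of the array. They lay a median of 144 spots apart, where random sets had a median of 158 and a 5th percentile of 141. The test of a defect planned before could not decide. Nearest members lay a median of 12.1 spots apart against 13.9 in random sets, and 0.163 of 10000 random sets had nearest members as close. Both distances were below the random medians. The 4 HI arrays held separate positions on their slide, and the groups did not overlap in any of the 199 genes. This argues against a defect at 1 place of the slide, which would not reach all 4 arrays. A fault at the same place within every array of a slide, behind part of these changes, is not excluded. The slide itself and group cannot be told apart, since 0 slides hold arrays of both groups, and differences in parentage are untested. The labels do not give the sex of the animals, and 0 genes of the sex-linked list were measured. A difference in sex between the groups was therefore not tested either.

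Choroid plexus genes differ between animals by more than any other list. The insult as the whole cause is argued against by Ttr, which was 7.51 log2 units higher in control 2 than in HI 1. The 6 measured genes of the list had a mean pairwise correlation of 0.686 over the 8 arrays, which is consistent with varying amounts of adjoining choroid plexus in the dissected samples. Meningeal tissue in HI 2 was not tested separately.

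Of the 35 ways to split the 8 arrays into 4 and 4, only the real one gave as many as 199 genes, and the highest other split gave 9. Chance is excluded for the gene count at the level of 1 of 35, the lowest this test can reach. The real split is also the split by slide and scan. A slide effect could therefore give such counts too, and the gene counts here do not tell HI from slide. For the 2-fold count the real split gave 411, again 1 of 35, and the highest other 182. Without control 1, 1 of 35 splits into 3 and 4 gave 793 genes, and the highest other gave 63. For the count of gene lists chance is not excluded: 7 of 35 splits gave 4 or more lists, up to 6.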

How the results depend on the processing

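The fit without control 1 and HI 2 together was chosen after seeing the data. The count of 199 genes stayed within 1.5 times under the other scalings, the authors' table, the filters, the probe choices and the intensity trend (145 to 205). The set changed more. Of the 199 genes 193 passed with the authors' table, 167 with the intensity trend, 151 after normexp with 75th percentile scaling and 130 with no filter. Of the 23 with a symbol 15 passed with the trend and 9 with no filter. The count was 1327 with array weights, in which control 1 had a weight of 0.0328, 308 at an adjusted p under 0.10, 705 without control 1 and HI 2, and 116 to 793 without 1 array. Higher genes were 42 of 199, 329 of 793 without control 1 and 572 of 1327 with array weights. The median of all changes was -0.0261, and -0.168 with no filter, where dim probes enter. The 2-fold count of 411 was 159 and 163 after normexp with quantile and 75th percentile scaling, 852 with no filter and 263 with probes well above background on all arrays. Normexp changed the spot signal, the background correction and the offset together, so their parts were not told apart. The 4 lists became 8 with no filter and 0 with an estimated correlation or fry, and 3 to 6 without 1 array. The 2-fold count was 374 to 554 without 1 array. List members past the threshold over all genes were 2 after normexp with either scaling, 1 with quantile scaling, 1 with the intensity trend, 19 with array weights, 13 without control 1 and HI 2, and 0 to 11 without 1 array. Unless the setting itself says it, the cause was not tested. Replicate numbers showed no pairing of the animals: same-numbered arrays correlated at -0.0488, -0.0335, -0.161 and 0.0266 in their deviations. No control array correlated best with the HI array of its own number. The replicate number is also the array's position on its slide, so the replicate block is a position block too. It gave 69 genes, among them 4 of the 23 with a symbol. Of 476 values of the 23 called named genes under alternatives 300 stayed past the threshold, 176 did not and 0 reversed. Of 1337 values of the other named genes 36 passed and 23 changed sign with neither fit past the threshold. Slide and scan blocks were not run. Signal over background limits dim genes, 20 of the lower and 3 of the higher calls being bounds.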

Other observations

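The test of the directions of neighbouring genes and the genes described first were chosen after the results were seen. Without control 1, 158 genes with a symbol passed limma's adjusted threshold, 89 higher and 69 lower. Among those higher after HI were the chaperone Hspa5 (log2 change 0.51, adjusted p = 0.0209), the disulfide isomerases Pdia6 (0.41, 0.0131) and Pdia5 (0.54, 0.0106), the oxidase Ero1a (0.55, 0.0208) and Creld2 (0.55, 0.025). These were not tested as a group, and the fixed list of heat shock and unfolded protein genes did not pass in this fit (median 0.18, adjusted p = 0.24). Of the fixed lists, 11 of 313 members passed over all genes in this fit, near the share over all genes (793 of 21794). Higher were the AMPA receptor subunit Gria1 (0.86, 0.0068), the glucocorticoid-induced Tsc22d3 (0.98, 0.00421), the microglial purinergic receptor P2ry12 (0.54, 0.0192), Hspa5 and Hsph1 (0.28, 0.048). Among those lower were Cox5a (-0.82, 0.000879), Rpl6 (-0.46, 0.0077), S100b (-1.09, 0.0219), Rps24 (-0.54, 0.0314) and Ier2 (-0.48, 0.038).

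Other genes that passed in this fit included the phosphatase Ppm1e (1.43, 0.00199) and Pex11a, of peroxisomes (1.09, 0.00488), both higher. Falls were found in Haus1, of the mitotic spindle (-1.38, 0.000563), and the protease inhibitor Spint1 (-1.11, 0.0277). The purinergic receptor P2rx4 (-0.84, 0.00525) and the transcription factor Jund (-0.75, 0.00489) were lower. With control 1 included none of these genes passed over all genes.

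A hypothesis was that the groups differ in inherited stretches of the genome, in which case called genes would lie near each other. Among these 158 genes 36 pairs lay within 5 measured named genes of each other on a chromosome, where 10000 random sets of 158 of the 5980 named genes had a median of 20 pairs, and a share of 0.0011 had as many. Sft2d2 with Adcy10 and Nat8f1 with Nat8b are such pairs. With all arrays, 1 pair was found among the 23 genes, and 0.341 of random sets had as many. Shared sequence or regulation that moves neighbours together, as the whole cause, is argued against by their directions: 11 of the 36 pairs moved the same way, where random assignments of the directions had a median of 18 and a share of 0.0093 had as few. The other 25 moved opposite ways, among them all 5 pairs adjacent among the measured named genes and Nat8b (-0.65) with Nat8f1 (0.91). Inherited stretches do not predict this excess of opposite directions either, so the source of the clustering stays open. The labels give neither the litters nor the sex of the animals, and parentage was not tested.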
